A study of Drosophila melanogaster with 12 samples.

How the data were processed

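The series holds 12 samples in 5 groups: ovary RNA-seq of germline Sfmbt RNAi and mCherry RNAi (3 each) and ovary ChIP-seq of Pho, of GFP-Sfmbt and of untagged chromatin with anti-GFP (2 each). Per the labels, RNA came from ovaries of 2-day-old females with the nanos-Gal4 driver, which is active in the germline, and ChIP chromatin was fixed for 10 min in 2% paraformaldehyde. The labels call the replicates biological.

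The gene table holds counts that the authors made with featureCounts 1.6.3 on STAR 2.7.2a alignments, per the file headers and the submitters' processing notes. Per the file headers the gene model was BDGP6.28, Ensembl release 101, and fragments were counted as reverse-stranded pairs with both ends mapped, within the allowed distance and not chimeric. The header sets no option to count fragments that map to several places or that overlap several genes on the same strand, so recent gene copies and overlapping genes are counted from their unique parts only. The summed exon length per gene in the deposited table was kept for reference and enters no test. Count columns are named by a letter and a number. C1 to C3 were read as the control, which the authors name in the design text and in the peak table for mCherry RNAi, and A1 to A3, the remaining RNA libraries, as Sfmbt RNAi; numbers were taken as replicate numbers. The labels do not explain the letter A, so this reading rests on elimination and not on the values. As a check afterwards, the fold changes from this reading were set against those that the authors' deposited table labels as Sfmbt RNAi over control: over 221 genes with a mean count of 10 or more, Pearson's r across genes was 0.948, and 90 of 93 genes with the authors' adjusted p under 0.05 had the same sign.

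The peak table holds RPM values that the authors made for Pho, GFP-Sfmbt and untagged chromatin, 1 per summit and group; whether the replicates were pooled or averaged, the peak caller and the window of the RPM are not given in the sources used here. Bowtie2 and deepTools 3.5.0 are named in the submitters' processing notes, with BDGP6 as the build. In each column all 352 RPM values of the deposited table were whole multiples of 1 step, within 0.01 step (steps of 0.125, 0.0153 and 0.0420 RPM for Pho, GFP-Sfmbt and untagged), so a low value rests on few steps and precision is lowest in the untagged column. The authors' rank scores order the summits by these values and served to take the stronger part of the list. The same deposited table gives, per gene, the authors' log2 fold change and their adjusted p-value, from a tool not given in the sources used here, and the authors' mean TPM per RNA group; these were used only for the check above. Summits carry the authors' gene assignment; 286 of the 289 genes were found in the count table.

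Of 17768 gene IDs in the count table, 17671 were matched to a symbol and 97 keep their ID. All 6 count columns were used. Totals were 51297961, 50669220 and 36660629 fragments in mCherry RNAi replicates 1 to 3 and 35801885, 34057506 and 47315104 in Sfmbt RNAi replicates 1 to 3. The libraries were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM normalization, robust dispersion estimates and the quasi-likelihood F-test, with group as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values are TMM-normalised, and errors of log2 fold changes are standard errors derived from the F statistic. A fold against 0 counts takes 3 counts over the group as the floor, and a fold against 1 to 3 counts carries an exact 95% counting interval; both cover counting error only. Within groups Spearman's rho across genes was 0.982 to 0.995, between groups 0.930 to 0.976, and no pair of replicates agreed within sampling noise (chi-square per gene of 27.8 or more). Same-numbered libraries deviated together from their group means, with correlations of 0.445, 0.301 and 0.103 for numbers 1 to 3, so by a rule fixed beforehand the numbers were treated as pairing the libraries in a second fit with the replicate number as a block; the labels do not say what a number shares, and only number 1 correlated best with its own.

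Gene lists were written before the data were examined: PhoRC, other Polycomb, Trithorax and canonical Polycomb target genes, synaptonemal complex and cohesin, meiotic recombination, germline stem cell and early cyst, oocyte and nurse cell, piRNA, testis, somatic gonad, eggshell, yolk, muscle sheath, hemocyte, fat body, neuron, gut and oviduct, apoptosis and DNA damage, stress, replication and cell cycle, RNAi line marker and mitochondrially encoded genes. Of 519 written members 510 were matched, 8 of them by a synonym. The 23 lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and again with the correlation estimated per list; 9 lists passed with the preset and 0 with the estimate (3 at an unadjusted p under 0.05). Genes with a summit were compared with the other tested genes by two-sided Fisher's exact tests. For the share of list members with a summit the background was all other gene IDs, tested or not. Named genes follow a rule fixed beforehand: Sfmbt, pho and phol; the 10 largest rises and 10 largest falls with adjusted p under 0.05, an average log2 CPM of at least 1 and separated groups; up to 4 genes per list with the smallest p; 10 summit genes with the smallest p; and all HOX and synaptonemal complex genes. A few further list members, such as bam, are named after their values were seen.

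The edgeR step was tested on 4 sets of simulated counts for the comparison of Sfmbt RNAi with mCherry RNAi, each drawn for 9667 genes with 200 changed. With dispersions on the fitted trend, 35.4% of 1.5-fold, 56.0% of 2-fold and 82.6% of 4-fold changes were recovered, and 24 of 487 calls were false. With each gene's own dispersion as the truth, 49 of 497 calls were false, a share above the nominal 5%. In a simulated list test a list of 20 genes shifted by 1.5-fold was called, and 2 of 100 unshifted lists fell below 0.05. Simulated genes were drawn independently, so this does not cover lists whose members vary together. Estimated correlations in the real data were 0.512 for the eggshell list and 0.639 for the replication list. Alternatives were RLE size factors, no filter, a filter at 1 CPM in 3 libraries, the block, leaving out each library, DESeq2 1.42.0, limma voom, leaving out eggshell and yolk genes, a test against 1.5-fold, and stronger or closer summits. Leaving out mitochondrial genes, the log2 chorion level as a covariate, summits at 2 times the untagged value and 8-fold calls, summits in lists with the canonical targets left out, and a fit with the summed gut enzyme CPM as a covariate were added after the data were seen. Tests of ChIP signal per sample were not run.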

Results

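Ovaries of Drosophila melanogaster females were profiled for RNA and for chromatin binding of a Polycomb complex. Sfmbt and the DNA-binding protein Pho together form PhoRC, the Polycomb complex that recognises Polycomb response elements. RNA-seq compared ovaries in which the nanos-Gal4 driver expressed a hairpin against Sfmbt in the germline with ovaries expressing a hairpin against mCherry, a protein that flies do not make. Each RNA group had 3 biological replicates from 2-day-old females, and totals ran from 34057506 to 51297961 counted fragments per library. ChIP-seq was made with anti-Pho on chromatin of yw ovaries and with anti-GFP on chromatin of GFP-Sfmbt knock-in and untagged ovaries, with 2 biological replicates for each of the 3 groups. The 2 lettered arms of the count table were read as the control and the Sfmbt RNAi arm from their letters, as described with the processing.

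The first comparison asked which transcripts change when the germline loses Sfmbt. Sfmbt itself, at 2L:13169649-13176785, fell in every Sfmbt RNAi library, with 43.8, 43.8 and 36.7 CPM in replicates 1 to 3 against 146.1, 122.4 and 123.2 CPM in the mCherry RNAi replicates (log2 fold change −1.66 ± 0.11 SE, edgeR adjusted p = 0.000119). Its partner pho fell as well, from 226 ± 28.7 to 134 ± 9.95 CPM (SD, n = 3; log2 fold change −0.75, edgeR adjusted p = 0.00271), while the pho paralog phol had a log2 fold change of −0.19 (edgeR adjusted p = 0.176). As a list these 3 genes, which include the RNAi target, were lower by camera (adjusted p = 0.0102, and adjusted p = 0.323 with an estimated correlation). Genes listed under the synaptonemal complex, early germline cysts and the testis programme stood among the rises, and replication, chorion and mitochondrial genes among the falls. Of 9667 genes tested, 3350 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1470 higher and 1880 lower in Sfmbt RNAi; with RLE scaling the split was 1645 and 1654. Of the genes called, 501 rose and 447 fell by 2-fold or more. The strong changes were mostly rises, with 185 genes at least 8-fold higher and 28 at least 8-fold lower. In 3333 of the called genes the 3 libraries of each group did not overlap, and over all tested genes 4858 were separated in this way, where chance gives 10%. Without mCherry RNAi replicate 2 the number called was 1756, and without mCherry RNAi replicate 3 it was 1931. With the chorion level of each library as a covariate, chosen after the data were seen, 213 genes were called, and the standard errors of the tested genes were 1.94 times as large at the median. Of 99 called genes that the rule for named genes took, 39 kept their call with this covariate, which itself differed between the groups, and pho was not among them (log2 fold change −0.48 ± 0.20 SE, edgeR adjusted p = 0.284). Of the 60 that lost it, 44 had at least 0.5 times their log2 fold change without the covariate.

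The synaptonemal complex, which holds homologous chromosomes together in meiosis, and the meiotic cohesins that carry it gave some of the clearest rises. Of 15 measured members of this list 7 rose, 3 fell and 5 did not pass the test, and the counts adjusted over the list alone were also 7 and 3. The cohesion protein gene ord (FBgn0003009, 2R:23271257-23275536) rose 125-fold, from 0.634 ± 0.0623 to 80.4 ± 9.46 CPM (SD, n = 3; log2 fold change 6.97 ± 0.14 SE, edgeR adjusted p = 5.52e-07). The central region genes cona and corolla rose 11.1-fold and 3.42-fold, and c(3)G, which encodes the transverse filament, rose 6.38-fold from 29.4 ± 1.84 to 187 ± 14.5 CPM (SD, n = 3). The lateral element gene c(2)M rose 1.38-fold, and the cohesin genes sunn and solo rose 2.24-fold and 1.91-fold. The genes that fell also act in mitosis: the cohesin subunit vtd and the acetyltransferase san had log2 fold changes of −0.42 and −0.32, and the condensin subunit barr −0.48. SMC1 and SMC3, the shared cohesin core, had log2 fold changes of −0.15 and 0.15 (edgeR adjusted p = 0.197 and 0.281), and those of Nipped-B, Cap-G and dmt were 0.10, −0.12 and −0.08. As a list these genes were higher than other genes by camera with a preset correlation (adjusted p = 0.00967), and the adjusted p = 0.547 with an estimated correlation. Calls for sunn and solo were lost without mCherry RNAi replicate 2 (edgeR adjusted p = 0.0613 and 0.0628), without mCherry RNAi replicate 3 (0.0758 and 0.0563) and without Sfmbt RNAi replicate 2 (0.0536 and 0.0506). With the chorion covariate sunn, solo and c(2)M lost their calls (edgeR adjusted p = 0.473, 0.385 and 0.205). Their log2 fold changes went from 1.17 ± 0.27, 0.93 ± 0.20 and 0.47 ± 0.09 to 0.90 ± 0.55, 0.79 ± 0.40 and 0.54 ± 0.18 (SE), so these calls ended mainly through larger errors. The falls of vtd, barr and san lost their calls as well (edgeR adjusted p = 0.637, 0.625 and 0.139): vtd and barr went to −0.16 ± 0.15 and −0.22 ± 0.19, smaller changes with larger errors, and san to −0.46 ± 0.12 (SE). ord, cona, c(3)G and corolla kept their calls.

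**Figure D1:**
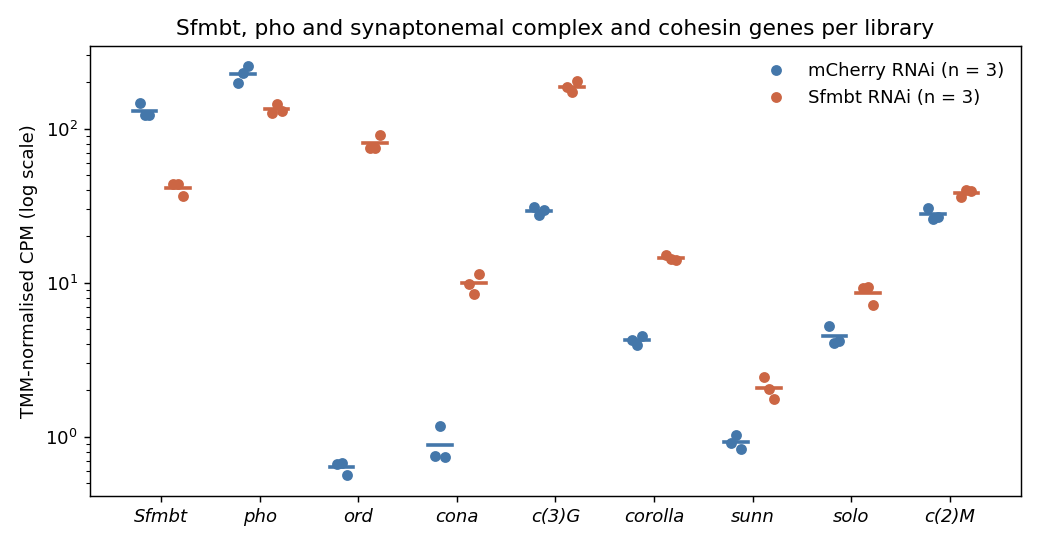
TMM-normalised CPM on a log scale for Sfmbt, pho and 7 synaptonemal complex and meiotic cohesin genes; each point is 1 library and each bar the mean of 3. The mean of ord was 0.634 CPM in mCherry RNAi and 80.4 CPM in Sfmbt RNAi, and Sfmbt itself went from 131 to 41.4 CPM.

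Other germline genes moved in both directions. Among 20 measured members of the germline stem cell and early cyst list 9 rose, 3 fell and 8 did not pass the test. The RNA-binding protein gene blanks, nearly silent in control ovaries, rose 65.2-fold from 0.280 ± 0.0209 to 18.5 ± 2.13 CPM (SD, n = 3). The transcription factor gene chinmo rose 27.3-fold from 1.18 ± 0.177 to 32.2 ± 3.4 CPM (SD, n = 3), and the cyst differentiation regulator Rbfox1 3.16-fold (log2 fold change 1.66 ± 0.07 SE, edgeR adjusted p = 1.56e-05). bam, which drives cyst formation, fell with a log2 fold change of −0.97. The list was higher by camera (adjusted p = 0.000972 with the preset and adjusted p = 0.323 with an estimated correlation). Of 35 piRNA pathway genes 16 rose, among them rhi and BoYb (log2 fold changes 0.93 and 0.80), and 3 fell, among them moon, which directs transcription of piRNA clusters, 6.11-fold, and squ 2.34-fold. The list test gave adjusted p = 0.00745, and adjusted p = 0.705 with an estimated correlation; with the chorion covariate the median log2 fold change of the list went from 0.19 to 0.03 and the call was lost (adjusted p = 0.434). Of 25 measured meiotic recombination genes 6 rose and 7 fell, with spn-B, Mcm5, trem and the chromokinesin gene nod at log2 fold changes of −1.26, −1.47, −0.76 and −1.12 (camera adjusted p = 0.718). The chorion covariate ended the calls of BoYb, spn-B, Mcm5 and trem (edgeR adjusted p = 0.195, 0.132, 0.0623 and 0.174), while rhi, moon, squ and nod kept theirs.

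Of 40 testis-specific genes listed, 14 were expressed highly enough to test, and 7 of these rose and 2 fell. The spermatocyte transcription regulators aly, tomb and comr rose: aly had 2 fragments over the mCherry RNAi libraries and 756 over the Sfmbt RNAi libraries, a ratio of CPM of 379 with an exact counting interval of 105 to 3134, and tomb rose 20.8-fold. With the chorion covariate comr lost its call (log2 fold change 2.46 ± 0.91 SE, edgeR adjusted p = 0.251), and aly and tomb kept theirs. CycB3 fell with a log2 fold change of −0.93, a call also lost with that covariate (edgeR adjusted p = 0.290). It is also on the replication list and had 232, 230 and 213 CPM in the mCherry RNAi libraries, so it is not confined to testis. The testis list was higher by camera (adjusted p = 0.0231 with the preset and adjusted p = 0.540 with an estimated correlation), and lost that call without mCherry RNAi replicate 1 (adjusted p = 0.0554), without mCherry RNAi replicate 2 (0.0534), without Sfmbt RNAi replicate 3 (0.0716) and with a filter at 1 CPM in 3 libraries (0.0844). Of 18 neuron genes listed, 8 were expressed highly enough to test, and 6 of these rose. They included the microtubule-binding protein gene futsch (log2 fold change 2.15 ± 0.31 SE), the calcium channel gene cac (0.96) and dlg1 (0.55). The list had camera adjusted p = 0.0027, and adjusted p = 0.323 with an estimated correlation. dlg1 had a mean of 113 CPM in mCherry RNAi, so it was already well expressed in control ovaries. futsch, cac and dlg1 lost their calls with the chorion covariate (edgeR adjusted p = 0.209, 0.206 and 0.0848). Their log2 fold changes were then 1.88 ± 0.62, 1.12 ± 0.37 and 0.57 ± 0.12 (SE), and the neuron list kept its call (camera adjusted p = 0.00115).

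In 3 lists the members moved mostly down. Of 27 genes of DNA replication and the cell cycle 19 fell, 0 rose and 8 did not pass the test; adjusted over the list alone, 20 fell and 2 rose. The replication factor genes Mcm5, Orc1, Orc2 and PCNA had log2 fold changes of −1.47 ± 0.13, −1.43 ± 0.13, −1.36 ± 0.12 and −0.99 ± 0.07 (SE, n = 3 against 3). camera gave adjusted p = 1.86e-09 for the list, and adjusted p = 0.547 with an estimated correlation. With the chorion covariate Mcm5, Orc1 and Orc2 lost their calls (edgeR adjusted p = 0.0623, 0.0563 and 0.0518). Their log2 fold changes were then −1.06 ± 0.203, −0.998 ± 0.183 and −0.997 ± 0.174 (SE). PCNA kept its call (−0.919 ± 0.131 SE, edgeR adjusted p = 0.0306), as did the list (camera adjusted p = 1.33e-07). The eggshell list fell in 14 of 23 members with 0 rises (camera adjusted p = 4.04e-05, adjusted p = 0.643 with an estimated correlation); it lost its call with the chorion covariate (adjusted p = 0.252), which is made from its own members. All 9 chorion genes of this list fell, and their summed CPM went from 40278 ± 6568 to 14703 ± 6829 (SD, n = 3), whereas 0 of 7 vitelline membrane genes, which follicle cells make earlier in egg development, passed the test (median log2 fold change −0.02). Cp36 lost its call without Sfmbt RNAi replicate 3 (edgeR adjusted p = 0.0633). Of 13 protein-coding genes of the mitochondrial genome 11 fell, with mt:ND5 from 4226 ± 402 to 1446 ± 543 CPM (SD, n = 3), with camera adjusted p = 1.43e-06 and adjusted p = 0.547 with an estimated correlation. mt:ND5 lost its call with the chorion covariate (log2 fold change −1.44 ± 0.62 SE, edgeR adjusted p = 0.318), and the mitochondrial list kept its own (camera adjusted p = 0.000144). Mitochondrial ribosomal RNA held 9.35%, 11.9% and 10.9% of fragments in the mCherry RNAi libraries and 6.18%, 7.50% and 4.35% in the Sfmbt RNAi libraries.

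**Figure D2:**
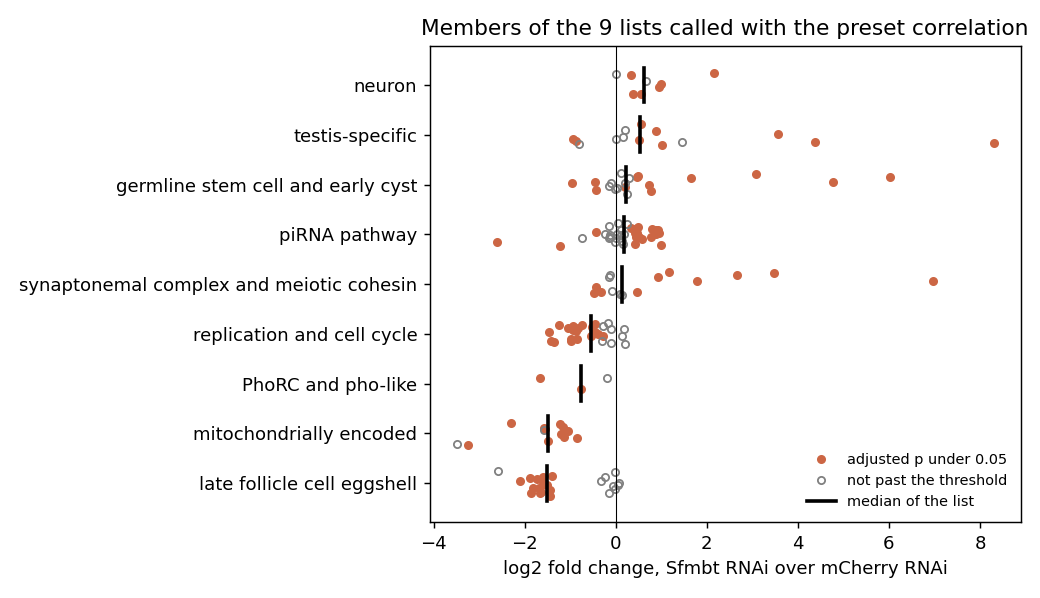
Log2 fold changes of every tested member of the 9 gene lists called by camera with a preset correlation; each circle is 1 gene, filled where its adjusted p was under 0.05, and the black bar is the median of the list. The median was −1.51 in the eggshell list and 0.61 in the neuron list.

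The lists of somatic gonad, yolk, muscle sheath, hemocyte, fat body and gut genes did not pass the list test, and the gut genes varied between libraries. Of the somatic gonad and early follicle cell genes 5 of 28 rose and 1 fell, with Notch (N) at a log2 fold change of 0.73 (camera adjusted p = 0.342). The yolk protein genes had 0 of 3 called (Yp1 0.54, edgeR adjusted p = 0.0759), muscle sheath 1 of 22 (Tm1, −0.36), hemocyte 0 of 13 and fat body 2 of 16 (Jhe, −2.25; Desat1, −0.36). Their camera adjusted p values were 0.342, 0.760, 0.327 and 0.538, in that order. Summed gut digestive enzyme transcripts were 140, 784 and 1467 CPM in the mCherry RNAi libraries and 0.894, 130 and 26.9 CPM in the Sfmbt RNAi libraries; the gut and oviduct list had 1 of 13 genes called (cv-c, −0.66; camera adjusted p = 0.0799), and with the replicate number as a block its adjusted p was 0.00432 (adjusted p = 0.694 with an estimated correlation). That list also passed without Sfmbt RNAi replicate 2 (camera adjusted p = 0.0153) and with no filter (0.0252). Without Sfmbt RNAi replicate 3 the yolk, muscle sheath and hemocyte lists passed as higher (0.0248, 0.0180 and 0.0114). With estimated correlations these adjusted p values were 0.770, 0.814, 0.527, 0.781 and 0.527, in the same order. Desat1 lost its call with the replicate block (edgeR adjusted p = 0.0708). Leaving out 1 library also ended calls: that of Jhe without mCherry RNAi replicate 2 (edgeR adjusted p = 0.0510), that of cv-c without mCherry RNAi replicate 2 or 3 or Sfmbt RNAi replicate 1 or 3 (0.0631 to 0.0849), and that of Desat1 without mCherry RNAi replicate 2 or 3 or Sfmbt RNAi replicate 2 or 3 (0.0538 to 0.113).

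Regulators and targets of the Polycomb system moved in both directions, and none of these 3 lists passed as a group. Of 19 other Polycomb group genes 4 were called: ph-p rose 4.87-fold, from 7.21 ± 0.504 to 35.1 ± 1.97 CPM (SD, n = 3), sxc and jing rose by less than that (log2 fold changes 0.52 and 0.61), and esc fell (−0.44). Of 16 Trithorax group genes 2 rose, among them trx (0.68), and 4 fell, among them the chromatin remodeller subunits Snr1 (−0.81) and Bap60 (−0.58). Of 67 canonical Polycomb target genes 24 were expressed highly enough to test: 3 rose, 3 fell and 18 did not pass. Over all tested genes 34.7% were called. The homeobox gene Gsc rose 304-fold, from 0.0313 ± 0.0114 to 10.4 ± 1.33 CPM (SD, n = 3), and ey rose 2.84-fold at a low level, from 0.584 ± 0.125 to 1.67 ± 0.0434 CPM (SD, n = 3). The homeobox gene ap (log2 fold change 1.01 ± 0.27 SE, edgeR adjusted p = 0.0266) lost its call when any 1 library but Sfmbt RNAi replicate 3 was left out (0.0676 to 0.106), with no filter (0.0509), with the replicate block (0.0714) and with the chorion covariate (0.556). The GATA factor gene srp had a log2 fold change of −1.18 ± 0.30 SE (edgeR adjusted p = 0.0290). srp lost its call without mCherry RNAi replicate 2 or 3 (edgeR adjusted p = 0.0931 and 0.0849), without Sfmbt RNAi replicate 1 or 3 (0.0735 and 0.118), with no filter (0.0537) and with the chorion covariate (−0.19 ± 0.33 SE, 0.819). That covariate also ended the calls of ey (1.35 ± 0.57), sxc (0.28 ± 0.13), jing (0.39 ± 0.21) and trx (0.46 ± 0.24, SE). The same held for esc (−0.42 ± 0.13), Snr1 (−0.54 ± 0.11) and Bap60 (−0.44 ± 0.11, SE). Their edgeR adjusted p values were 0.0781 to 0.424, and ph-p and Gsc kept their calls. No change was detectable in the 4 HOX genes tested: abd-A, Antp, Abd-B and Ubx had log2 fold changes of 0.20 ± 0.36, −0.22 ± 0.44, −0.20 ± 0.41 and 0.05 ± 0.52 (SE, n = 3 against 3; edgeR adjusted p = 0.707 to 0.953), while lab, pb, Dfd and Scr lay below the count filter, with 29, 3, 4 and 0 fragments over all 6 libraries. The 3 lists had camera adjusted p values of 0.327, 0.975 and 0.725.

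The 10 largest rises were genes nearly silent in the control. hog and CG43088, near each other on X, rose from 0.102 ± 0.0656 to 113 ± 4.42 CPM and from 0.0718 ± 0.0247 to 159 ± 33.7 CPM (SD, n = 3). CG15599, CG13540, CG42857, CG42854 and CG32971 rose to between 61.8 and 343 CPM, from 0.511 CPM or less. CG15056 and TfIIA-S-2, a paralog of a general transcription factor subunit, each had 2 fragments over the mCherry RNAi libraries and 3169 and 2711 over the Sfmbt RNAi libraries, ratios of 1588 (exact counting interval 439 to 13117) and 1358.4 (376 to 11222). CG43843 had 0 fragments in mCherry RNAi and was at least 216-fold higher in Sfmbt RNAi, taking 3 counts over the group as the floor. Of the 10 largest falls, asRNA:CR43767, lncRNA:CR44445 and CG11034 (log2 fold changes −7.23 ± 0.49, −5.97 ± 0.35 and −2.79 ± 0.11, SE) kept their calls when any 1 library was left out; the other 7 (CG33346, CG31104, Alp10, CG5391, Mdr50, mt:ND2 and CG31928) each lost it in at least 1 such fit.

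**Figure D3:**
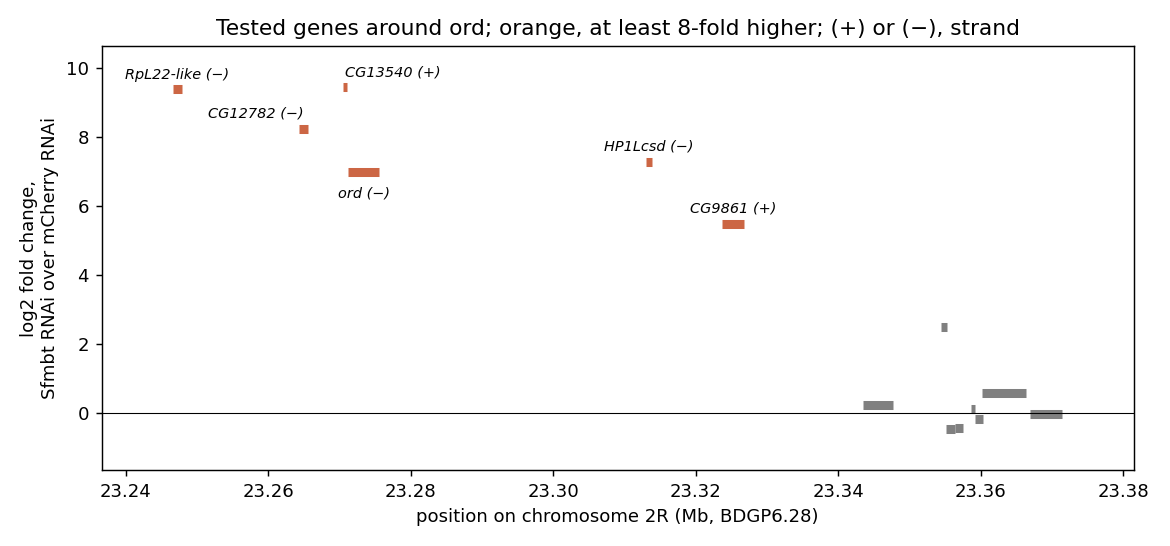
Tested genes within 0.1 Mb of ord on chromosome 2R, drawn to scale (position in Mb of BDGP6.28) at their log2 fold change; orange genes were at least 8-fold higher, and the sign after a name is the strand. The 6 orange genes lie side by side, from CG9861 at 5.49 to CG13540 at 9.45, and the other 8 genes drawn lie between −0.48 and 2.48.

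The second comparison asked where Pho and Sfmbt bind in ovaries. The authors' table lists 352 summits at 351 positions and 289 genes, each with 1 RPM value per antibody and genotype and no value per replicate, so the groups were not tested against each other. The strongest by both antibodies lay at 3R:16869537, assigned to abd-A at a distance of 39488 bp, with 125 RPM for Pho and 7.72 RPM for GFP-Sfmbt against 0.420 RPM for anti-GFP on untagged chromatin. Next came summits at 3R:16764172, assigned to CG31275 (58.0 and 7.61 RPM), and 3R:16948777, inside Abd-B (62.8 and 6.59 RPM). By the mean of both ranks another summit assigned to Abd-B, at 3R:16899962 (47.3 and 5.06 RPM), followed, and then those assigned to the homeobox gene oc and, tied, to the homeobox gene cad and to Prat2. Abd-B, Antp and abd-A had 8, 6 and 5 summits. Over all summits the median was 4.52 RPM for Pho, 0.886 RPM for GFP-Sfmbt and 0.336 RPM for the untagged control. GFP-Sfmbt exceeded the untagged value at 331 of 352 summits (94.0%, exact Clopper-Pearson 95% interval 91.0 to 96.3%, which covers counting error only), and was at least 2 times that value at 238. The authors had already selected these summits, by a rule not given in the sources used here. The share therefore describes their list and is no test of binding. Pho and GFP-Sfmbt values went together across summits (Spearman rho 0.678), while Pho and the untagged control had a rho of 0.0574; summits are not independent replicates. Of 67 canonical Polycomb target genes 39 had a summit, 58.2% against 1.40% of other genes (two-sided Fisher's exact test adjusted over 23 lists, p = 7.32e-52). By the same test 6 further lists carried summits more often than other genes: somatic gonad and early follicle cell (7 of 29, adjusted p = 3.45e-06), Trithorax group (5 of 16, 3.02e-05), other Polycomb group (4 of 19, 0.00121), oocyte and nurse cell (4 of 32, 0.00762), germline stem cell and early cyst (3 of 20, 0.0147) and replication and cell cycle genes (3 of 27, 0.0298). The other genes here were the rest of the 17768 gene IDs, with the 8101 below the count filter included. A background of tested genes only was not tried, and the smaller excesses may depend on this choice. CycB, with 2 summits, counts in both the oocyte and the replication list, so those results are not independent. The somatic gonad list shares ct, en, eya, hh and mirr with the canonical targets. With all canonical targets left out, chosen after the data were seen, 4 of its 24 other members had a summit (adjusted p = 0.000631 over 6 lists).

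**Figure D4:**
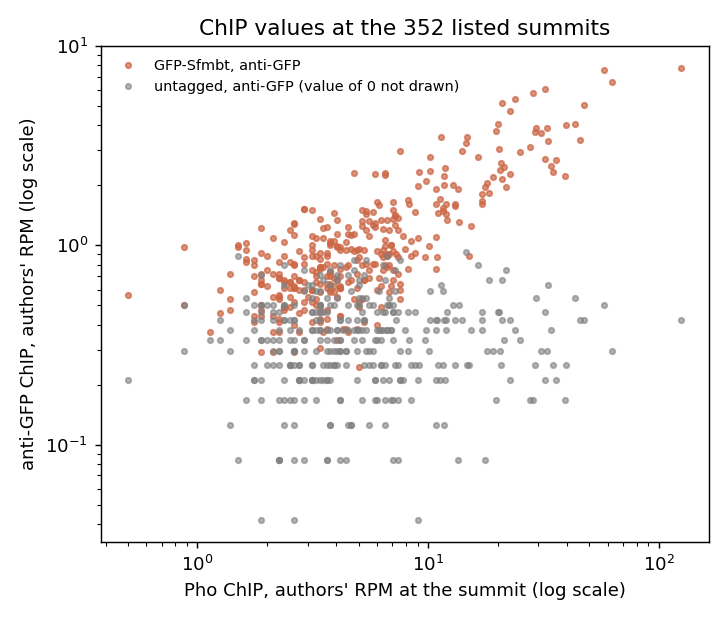
The authors' RPM at 352 summits on log axes: Pho ChIP on the horizontal axis, and anti-GFP ChIP from GFP-Sfmbt (orange) and untagged ovaries (grey) on the vertical axis; each point is 1 summit. The GFP-Sfmbt values reach 7.72 RPM where Pho is strongest, and the untagged values stay at or below 0.924 RPM.

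The third comparison asked whether genes with a Pho and Sfmbt summit changed in Sfmbt RNAi. The summit genes that changed most clearly were rises: CG32814 rose 69.0-fold, dpr18 63.0-fold, chinmo 27.3-fold, Cph 9.72-fold, the amyloid precursor protein gene Appl 7.0-fold, the cell death gene hid 5.07-fold and ph-p 4.87-fold, and Gsc and Rbfox1 belonged to the same set. nod fell 2.17-fold. The summit at cona lay 5 bp from its annotated 5' end, with 6.27 RPM for Pho and 0.901 RPM for GFP-Sfmbt against 0.378 RPM untagged; that of hid had 0.504 RPM in both anti-GFP columns, and that of Cph 0.458 RPM for GFP-Sfmbt against 0.420 RPM untagged. As a set, summit genes were not shown to differ from other genes in this test. Of the 286 summit genes in the counts 65 lay below the count filter and were not tested. ChIP and RNA came from ovaries with somatic and germline cells, and the hairpin was driven in the germline. Summits in somatic cells, where no Sfmbt loss was driven, therefore cannot be told apart from germline summits. This limit holds for the HOX genes above as well. Of 221 summit genes tested 38 rose (17.2% against 15.2% of other genes; odds ratio 1.16, 95% interval 0.793 to 1.66, two-sided Fisher's exact p = 0.394) and 37 fell (16.7% against 19.5%; odds ratio 0.830, interval 0.564 to 1.19, exact p = 0.344). camera gave p = 0.216. For the stronger part of the summits the odds ratio was 1.54 for rises (exact p = 0.0943) and 0.602 for falls (exact p = 0.101). The odds ratio for rises passed the threshold without a low-count filter (1.47, exact p = 0.0336), without mCherry RNAi replicate 1 (1.54, exact p = 0.0130) and with the chorion covariate (3.72, exact p = 0.000402). Falls of 2-fold or more were found in 4 summit genes (odds ratio 0.375, exact p = 0.0492, adjusted p = 0.246 over 5 tests, of which the 8-fold one was chosen after the data were seen).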

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

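The mitochondrial, chorion covariate, 2 times untagged and 8-fold settings were chosen after seeing the data. The number of genes called, 3350, ran from 1756 to 3295 when 1 library was left out (706 to 1452 higher, 1050 to 1843 lower), with 1756 without mCherry RNAi replicate 2 and 1931 without mCherry RNAi replicate 3. It was 2959 with the replicate block, where 2723 calls were shared and all had the same direction, and 3299 with RLE, 3813 with DESeq2 and 3318 with limma voom. The test against 1.5-fold called 591 (341 higher, 250 lower, 521 at 2-fold or more), since it asks for a larger change. With the chorion level as a covariate 213 were called (142 higher, 71 lower, 177 at 2-fold or more), and the cause was not tested. Of 9 called lists, 0 were called with an estimated correlation, and 8 to 11 when 1 library was left out. Under the block ap and Desat1 lost their calls, alphaTry, betaTry, Mal-A1 and FASN1 gained one, and the gut list passed; it changed no other call of a named gene or list. Of 99 called named genes 84 to 97 kept their call when 1 library was left out, 55 in the test against 1.5-fold and 39 with the chorion covariate, and 0 changed sign. The odds ratio of summit genes among rises was 1.16 and passed with no filter (1.47), without mCherry RNAi replicate 1 (1.54; leave-one-out range 1.15 to 1.54) and with the chorion covariate (3.72). Among falls it was 0.830, lay above even odds without mCherry RNAi replicate 2 (1.10) and 3 (1.02; range 0.819 to 1.10) and with the covariate (1.90), and was 0.375 for falls of 2-fold or more. Among the 176 summits with the better mean ranks GFP-Sfmbt exceeded the untagged value at 98.9%. Those ranks include the GFP-Sfmbt rank itself, so a higher share follows from the choice and is no check of it. Signs turned only for results that had not passed the test. The camera direction turned for these lists, given with their median log2 fold changes: Trithorax (0.098 with RLE, 0.0786 with the strict filter, 0.0637 with the block, 0.0910 without mitochondrial genes; leaving out 1 library 0.0293 to 0.13), heat shock (leaving out 1 library −0.37 to 0.16), canonical Polycomb targets (−0.27 to 0.22) and muscle sheath (−0.22 to 0.32, past the threshold without Sfmbt RNAi replicate 3), and with the chorion covariate gut (1.87, past the threshold, adjusted p = 0.931 with an estimated correlation) and apoptosis (−0.000155). Medians of 8 lists changed sign in 18 cases with the camera direction kept, among them hemocyte (−0.19), somatic gonad (−0.16) and Trithorax (−0.06) with the chorion covariate; 0 of these were called in either fit. Among genes Yp3 turned with RLE (0.00873) and DESeq2 (0.00873) and Ubx with voom (−0.0289). Leaving out 1 library turned Ubx (−0.40 to 0.40), Abd-B (−0.54 to 0.0801), v (−0.31 to 0.15), Yp3 (−0.14 to 0.18), abd-A (−0.10 to 0.51), Cap-G (−0.23 to 0.0136), dmt (−0.17 to 0.0396) and Antp (−0.54 to 0.0985). The chorion covariate turned abd-A (−0.19), alphaTry (2.25), betaTry (2.42), Cap-G (0.0393), crq (0.0741), dmt (0.0429), FASN1 (−0.18), Mal-A1 (1.10), vkg (−0.30), y (0.0252) and Zasp52 (0.14). For these the cause was not tested. Planned tests of summit class, of interval overlap and of ChIP signal per sample were not run, as the table gives summits with 1 value per group. Genes below the count filter, among them 4 HOX genes and all but 14 of 40 testis genes, were not tested.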

Other observations

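Tests on the chorion level, the library scaling and gut tissue and the counts over other splits of the libraries were chosen after their results were seen; those on neighbouring genes and on the X chromosome were fixed after the pattern was noticed and before the test was run.

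Several other gene groups moved in parts. Among 30 measured oocyte and nurse cell RNAs 8 rose and 10 fell: pgc, which represses transcription in germ cells, fell 2.89-fold from 697 ± 99.4 to 241 ± 40.7 CPM (SD, n = 3), mtrm, a Polo inhibitor of the oocyte, fell 2.64-fold, and the cell cycle regulators gnu and plu had log2 fold changes of −0.92 and −0.78 (camera adjusted p of the list 0.676). Of 21 apoptosis and DNA damage genes 4 rose and 6 fell: hid, Dcp-1 and p53 rose (log2 fold changes 2.34, 0.89 and 0.68) and the ribonucleotide reductase gene RnrS fell 2.16-fold (camera adjusted p 0.743). Of 19 stress genes GstD2 rose 9.52-fold while its neighbour GstD1 fell 2.11-fold, and Hsp26 fell 2.7-fold from 1620 ± 115 to 600 ± 44.6 CPM (SD, n = 3; camera adjusted p 0.676). Of the RNAi line marker genes w had a log2 fold change of −0.24 (edgeR adjusted p = 0.0171), and y and v did not pass the test (list adjusted p 0.676); w lost its call without mCherry RNAi replicate 2 or 3 or Sfmbt RNAi replicate 1 or 2 (edgeR adjusted p = 0.0510 to 0.0796). In the Trithorax, canonical Polycomb target, meiotic recombination, muscle sheath and apoptosis lists the median, the mean and the camera direction differed in sign.

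Of the 185 genes at least 8-fold higher, called risers here, 10 belonged to a list fixed beforehand, among them ord, cona, blanks, chinmo, bgcn, aly, tomb and comr, and 7 had a Pho and Sfmbt summit. Such rises were found in 3.17% of tested summit genes and 1.88% of other genes (odds ratio 1.70, 95% interval 0.667 to 3.64, two-sided Fisher's exact p = 0.204), so an excess was not shown.

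The strongest risers lay next to each other more often than random placement gives. Ordered along the chromosomes among 9667 tested genes, the 185 risers made 36 adjacent pairs, against a mean of 3.53 and a highest value of 14 in 10000 random placements (permutation p = 1e-04, the smallest these can give), which argues against chance placement. Of these pairs 19 were on opposite strands, with a highest random value of 8 (permutation p = 1e-04); since fragments were counted by strand, read-through from 1 riser into the next cannot account for those pairs, though it stays open for the 17 on the same strand. The longest run held RpL22-like, CG12782, CG13540, ord, HP1Lcsd and CG9861 on 2R, 6 genes of which 0 had a summit. What sets these neighbours apart was not tested.

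Risers were also more often X-linked: 61 of 185 (33.0%) against 17.5% of tested genes (odds ratio 2.36, 95% interval 1.70 to 3.25, two-sided Fisher's exact p = 2.55e-07). With each run of adjacent risers counted once the share on X was 29.5% (44 of 149 runs, exact binomial p = 0.000325), so repeated counting of neighbours does not account for it. The median of X-linked genes lay 0.11 above that of autosomal genes on the log2 scale, far from an 8-fold change, which argues against a shift of the whole chromosome, and of 447 genes at least 2-fold lower 18.1% were X-linked. The excess may reflect where these genes sit or what the fly lines carry on X, and neither was tested.

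Chorion and mitochondrial transcripts fell together in Sfmbt RNAi. The weakest median log2 fold change was −1.56 for the chorion genes over 4 scalings and −1.46 for the mitochondrially encoded genes over 3. The choice among these scalings thus accounts for neither fall. They lay close together, with all-gene medians of −0.04 (TMM), −0.006 (RLE and DESeq2) and −0.01 (mitochondrial genes left out). An error that all of them share was not tested. With the summed gut enzyme CPM of each library as a covariate the median of the gut enzyme genes went from −4.34 to −1.43. The chorion median was then −1.33 (SD over genes 0.244). Since the gut enzyme genes themselves stayed at −1.43, the covariate did not remove the gut difference. This fit therefore cannot decide whether gut tissue plays a part in the chorion fall. For the mitochondrial genes the median went from −1.49 to −1.13 (camera p = 2.40e-07 with the preset correlation). Their SD over genes was 1.18, which is a spread between genes and no error of the median. As the covariate left much of the gut difference in place, gut tissue stays open for those genes too. Vitelline membrane genes lay 1.58 above chorion genes (SD of the chorion genes 0.218), as fewer late egg chambers in the Sfmbt RNAi ovaries would give, so this stays open for the chorion genes. Of the 185 strongest risers 169 kept an 8-fold rise with the chorion level as a covariate and 54.6% kept their call, so the share of late egg chambers does not account for most of them; whether the difference lies in Sfmbt or elsewhere between the fly lines cannot be told apart, because 1 RNAi line against Sfmbt was sequenced.

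The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. In edgeR the real split called 3350 genes and the highest of the other splits 0 (7 to 604 genes at an unadjusted p under 0.05, against 4420; other tools were not run on them), and it called 75 summit genes against 0. Every other split puts libraries of both RNAi groups on each side, so the group difference widens the spread within sides. Their 0 calls therefore do not show how many genes would be called by chance. For lists tested with the preset correlation the real split called 9 and the highest of the others 14; 4 splits called 9 or more, the real one included. Whether the replicate numbers pair the libraries is not known, as only number 1 correlated best with its own. Every other split, those that part all 3 same-numbered pairs included, called 0 genes.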
